A study of Homo sapiens with 12 samples.

How the data were processed

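Total RNA of MDA-MB-231 cells, a human breast cancer line, was measured on 12 Illumina bead arrays of 1 colour. The design crossed an siRNA (control or p53) with a treatment (none or tumour necrosis factor, TNF) and gave 4 groups of 3 arrays. Each array's group was taken from its source name, and its replicate number from the description field, which calls the arrays biological replicates. The labels' protocols give growth in 10% serum, a move to 0.1% serum with or without TNF at 10 ng/ml at 48 h after transfection, and a further 20 h of culture. The protocols also record extraction with Qiazol, a gel check of RNA integrity and a biotin label read with Cy3-streptavidin.

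The deposited signal table holds, per the file headers, 1 intensity and 1 detection p-value for each of 47322 probes on each array. GenomeStudio is named in the submitters' processing notes, with no version given in the sources used here, and the intensities were treated as linear and not normalised because their medians differed between arrays. How the authors' software computed the detection p-values is not given in the sources used here. A second deposited table, the authors' processed intensity values, holds 47313 of these probes and lacks 9. Each of its columns has a median of 241.6, and each correlated with the signals of the same array at 0.999 or more over probes on the log2 scale, so its scale is linear, its columns run the same way as the signals and nothing was centred on genes. How the authors normalised that table stays unknown, and it was used only as an alternative.

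Background correction and normalisation used neqc of limma 3.58.1 in R 4.3.3, which takes the detection p-values as ranks against negative control probes and infers the background from them, adds an offset of 16, applies quantile normalisation and takes log2. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, which left 23079. Probe names came from the platform annotation table supplied for these probes, which can be old. It names 1 gene for 30107 probes and several for 8, and 17207 probes of the signal table carried no name here. Of the probes with 1 gene, 30068 matched a current human gene by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols changed. Of the kept probes, 16849 had 1 gene and 6230 had none or several and were left out. Where a gene had more than 1 kept probe, as 3384 did, the probe with the highest mean over the 12 arrays stood for it, and the text gives the other probe's change where it differed. This gave 12507 genes. No positions are given, since the sources used here name no genome build. The transcript that the p53 siRNA targets is not reported here, so the groups are named by their labels and the depletion was not checked.

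One linear model with a mean for each group was fitted to all 12 arrays with lmFit and eBayes of limma, so that the groups shared 1 estimate of the spread, with 8 residual and 4.03 prior degrees of freedom. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. There were 5 comparisons. They were the TNF effect in control siRNA cells, the TNF effect in p53 siRNA cells, the p53 siRNA effect in untreated cells, the p53 siRNA effect in TNF-treated cells, and the TNF response difference, which is the TNF effect in p53 siRNA cells minus that in control siRNA cells. Errors beside log2 changes are standard errors from that model. The 2 TNF effects share no array, and neither do the 2 siRNA effects, so the overlap of their calls is given beside the number that independent calls would share.

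A gene undetected on all 3 arrays of a group by all of its probes has only a bound there. Its change is given as "at least N-fold", which is the mean normalised log2 value of the brighter group against the mean, over the dim group's arrays, of the higher of the gene's own value and the lowest value of a detected probe on that array. No fold is given where both groups were undetected. With such genes at their bound, or left out of the TNF response difference, 90 of the 105 list medians moved by 0.05 or less.

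Gene lists, 21 of them with 20 to 42 members each, were written before the data were examined, as were the tests of the 5 comparisons, the alternatives and the rule for naming genes. Of the tests of explanations, 3 were chosen after the results they bear on were seen. Of their 578 genes, 463 were tested. The lists covered NF-kB regulators, cytokines and chemokines, interferon-stimulated genes, class I antigen presentation, acute phase and innate defence, adhesion with matrix proteases and invasion, wild-type p53 targets, cholesterol synthesis, proteasome subunits, G2/M and mitosis, DNA replication and G1/S, death receptors and apoptosis regulators, JNK and AP-1, TGF-beta response, epithelial markers, mesenchymal markers, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock and oxidative stress, leukocyte markers, and fibroblast and endothelial markers. The last 2 mark other cell types. Each list was tested against all other genes with camera at a preset correlation of 0.01, and again with an estimated correlation. The fry test, which does not compare a list with other genes, was an alternative. TNF-induced and TNF-repressed genes were those with a called mean TNF effect over both siRNAs of at least 1 on the log2 scale, a choice that weighs both siRNAs alike. It favours neither siRNA only where the groups have equal spread. The untreated p53 siRNA arrays had root mean square deviations from their group mean of 0.237 to 0.324, against 0.156 to 0.170 on the others. The choice can therefore lean toward genes whose response in p53 siRNA cells is raised by noise.

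Genes were named by rule. The rule took 17 sentinel genes of TNF and p53 biology, of which 13 were tested, and the 10 called genes with the largest rise and the 10 with the largest fall among those whose arrays did not overlap between groups, a separation that chance gives to 10% of genes. It also took up to 4 members of each list in order of p, and all genes called for the TNF response difference. Genes named for control siRNA cells could be given again for p53 siRNA cells. The text gives those the comparisons turn on.

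The scripts were tested on simulated arrays of all 12507 genes with the real means and spreads. For the TNF effect in control siRNA cells, 82.1% of genes changed 2-fold and 40.3% of genes changed 1.5-fold were called, with 1 false call. For the TNF effect in p53 siRNA cells these were 73.1% and 41.8%, with 33 false calls, for the p53 siRNA effect in untreated cells 80.6% and 34.3%, with 19, and for that in TNF-treated cells 82.1% and 37.3%, with 4. For the TNF response difference 47.8% of 2-fold, 16.4% of 1.5-fold and 86.4% of 4-fold differences were called, with 6 false calls. A list shifted in the simulation was found in each comparison and 0 other lists were called. The simulated genes varied independently, so the 0 says nothing about lists whose members correlate, as replication genes did on the real arrays (estimated 0.315). The number of arrays limits the precision, with a median standard error of 0.161 for a TNF or siRNA effect and 0.228 for the TNF response difference.

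The alternatives were quantile normalisation without background correction, the same background correction with scaling of each array to a common median, the authors' processed values, no detection filter, a filter of detection p under 0.01 on all 12 arrays, all kept probes, the mean of a gene's probes, the replicate number as a block, a fit of only the compared groups, array weights, an intensity trend with robust moderation, a threshold of 0.01, a minimum log2 change of 1, each array left out in turn, other ways to choose the TNF-induced genes, and the other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.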

Results

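MDA-MB-231 is a human breast cancer cell line that carries a mutant form of the tumour suppressor p53. The study asked how that mutant p53 bears on gene expression induced by TNF, an inflammatory cytokine that signals through the transcription factor NF-kB. Cells given a control siRNA or a p53 siRNA were left untreated or exposed to TNF for 20 h at 10 ng/ml, and total RNA was read on Illumina bead arrays, where each probe gives a fluorescence intensity. Each of the 4 groups held 3 arrays. The labels call them biological replicates, and the p-values measure the spread between these arrays. Effects of either siRNA that do not pass through p53 are not separated from those of p53 in any comparison of the siRNAs. The files used here give no slide or batch, so a batch shared by the arrays of a group is not excluded.

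The arrays were of similar brightness, with median intensities from 226 to 266 and between 19810 and 21157 of 47322 probes detected. Across the 12507 genes tested, which are not independent replicates, arrays of the same group correlated at 0.992 to 0.993 in 3 of the groups. In the untreated p53 siRNA group replicates 1 and 2 correlated at 0.987, and replicate 3 correlated with them at 0.974 and 0.977. On replicate 3 of that group 551 genes lay at least 2-fold from the mean of the other two arrays, against at most 47 for any TNF-treated p53 siRNA array. Relative to the mean of the other two, its medians over the 21 gene lists ran from -0.29 for leukocyte markers, -0.28 for DNA replication and -0.22 for interferon-stimulated genes to 0.17 for the acute phase list and 0.18 for mesenchymal markers on the log2 scale. The first principal component, with 50.1% of the variance, separated the siRNAs, and the second, with 19.2%, separated the treatments.

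**Figure D1:**
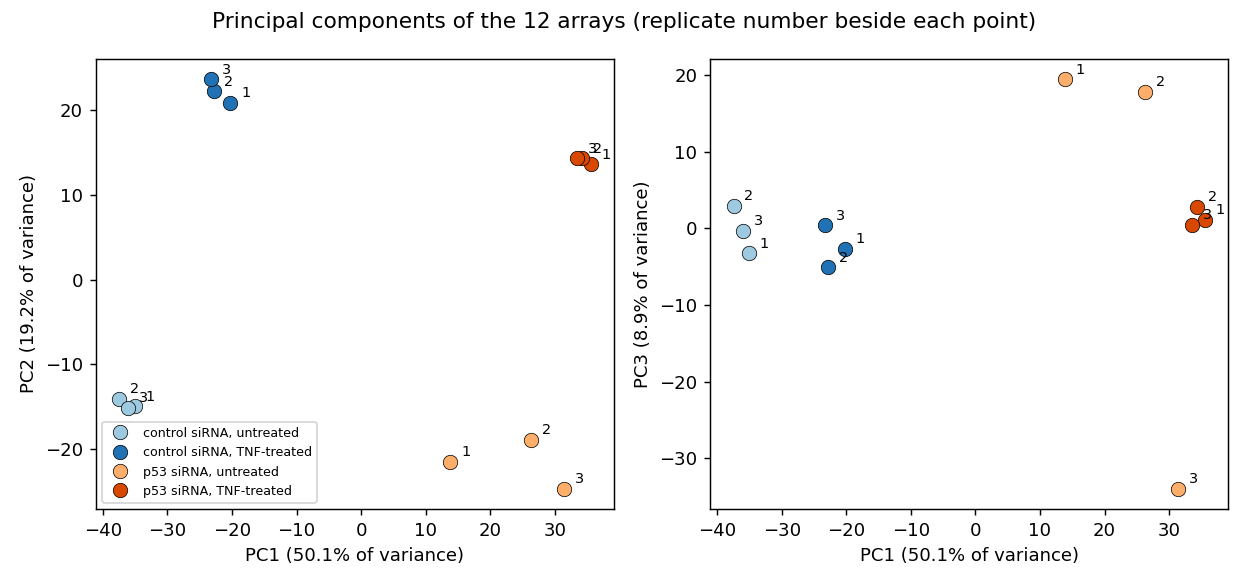
Principal components of the 12 arrays over 12507 genes, with the first component against the second (left) and the third (right), each point an array with its replicate number. Untreated p53 siRNA replicate 3 lay at -34.0 on the third component, and the other 2 arrays of its group at 19.5 and 17.9.

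The first comparison asked what TNF did in control siRNA cells, and it raised cytokines, chemokines and regulators of NF-kB. LTB, which encodes lymphotoxin beta, rose by 5.54 ± 0.20 on the log2 scale (SE, 3 arrays against 3). Another LTB probe gave 3.77, and the gene was detected on 1 of the 3 untreated arrays. IL32, a cytokine gene, rose by 4.78 ± 0.20 and was likewise detected on 1 untreated array. The chemokine genes CXCL10 and CXCL8 rose by 4.36 ± 0.15 and 3.84 ± 0.14. The cytokine genes IL1B and IL6 rose by 3.75 ± 0.11 and 3.63 ± 0.17, and PTGS2, the inducible cyclooxygenase, by 3.72 ± 0.16, each of these with an adjusted p of 7.5e-08 or less. CGNL1, a component of cell junctions, fell by 2.64 ± 0.14 (adjusted p = 1.62e-07), and ALDH3A1, an aldehyde dehydrogenase, was at -2.34 ± 0.22.

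Of 27 measured cytokines and chemokines 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 2.23 (camera adjusted p = 1.79e-35). Some transcripts undetected on all untreated arrays were detected on all TNF arrays. Among them the interleukin 1 alpha gene IL1A was at least 10.6-fold higher and EBI3, which encodes a cytokine subunit, at least 9.98-fold higher. MMP9, a matrix metalloprotease, was at least 6.06-fold higher (adjusted p = 1.31e-09). Among 20 NF-kB regulators 15 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.94, adjusted p = 1.18e-24). These included the inhibitors NFKBIA at 1.69 ± 0.12, TNFAIP3 at 2.87 ± 0.15, detected on 2 of 3 untreated arrays, and TNIP1 at 2.15 ± 0.10, and RELB, an NF-kB subunit, at 2.50 ± 0.12. In the acute phase list 15 of 19 rose (15 up and 1 down adjusted over the list alone; median 1.10, adjusted p = 8.11e-21). The serum amyloid gene SAA1 was at 2.70 ± 0.18 and the mitochondrial superoxide dismutase SOD2 at 2.53 ± 0.11. In the adhesion and matrix protease list 14 of 19 rose (14 adjusted over the list alone; median 0.84, adjusted p = 2.86e-16). Its members include the adhesion receptor ICAM1 at 3.18 ± 0.20, the collagenase MMP1 at 1.70 ± 0.21, detected on 1 of 3 untreated arrays, and the protease inhibitor SERPINE2 at 1.66 ± 0.15.

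TNF also raised 9 of 23 death receptor and apoptosis regulators in control siRNA cells (9 up and 1 down adjusted over the list alone; median 0.26, adjusted p = 2.04e-05). They included TNFRSF9, a TNF receptor family member, at 2.42 ± 0.13, CFLAR, an inhibitor of caspase 8, at 0.75 ± 0.12, and BID, a pro-apoptotic BCL2 family member, at 1.42 ± 0.12, for which another probe gave 0.18. TRAF1, an adaptor of TNF receptors, rose by 2.25 ± 0.23, where another probe gave 1.16. In the unfolded protein list 7 of 22 rose and 1 fell (12 and 3 adjusted over the list alone; median 0.42, adjusted p = 5.35e-05). The chaperone HSPA5 was at 0.85 ± 0.13, its cofactor DNAJB9 at 0.82 ± 0.14 and the transcription factor CEBPB at 1.34 ± 0.14. Genes of cell division fell. Of 33 DNA replication genes 28 fell and 0 rose (29 and 0 adjusted over the list alone; median -0.82, adjusted p = 5.94e-25). The helicase subunit MCM2 was at -1.15 ± 0.12, the polymerase subunit POLE2 at -1.06 ± 0.11 and thymidylate synthase, TYMS, at -0.99 ± 0.13. Of 35 mitosis genes 15 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.53, adjusted p = 8.46e-14). Topoisomerase TOP2A was at -0.84 ± 0.13 and the kinase AURKB at -0.66 ± 0.12. The trefoil peptides TFF2 and TFF3 were at -1.78 ± 0.14 and -1.76 ± 0.14.

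Smaller shifts were seen in 4 further lists in control siRNA cells. Class I antigen presentation had 5 of 19 members up (6 adjusted over the list alone; median 0.29, adjusted p = 2.76e-06, but adjusted p = 0.0880 with an estimated correlation). HLA-B was at 1.13 ± 0.13 and HLA-F at 0.76 ± 0.12. Interferon-stimulated genes had 4 of 37 up (4 adjusted over the list alone; median 0.17, adjusted p = 0.0313, but adjusted p = 0.415 with an estimated correlation). The GTPase GBP2 was at 0.74 ± 0.10 and the exonuclease ISG20 at 1.04 ± 0.18. Proteasome subunits had 0 of 28 called and 0 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.0112, and adjusted p = 0.0452 with an estimated correlation). Cholesterol synthesis had 2 of 20 up (2 adjusted over the list alone; median 0.16, adjusted p = 0.0331, but adjusted p = 0.0706 with an estimated correlation). The other 9 lists were not called by camera. Fry, which tests whether members move one way and compares them with no other genes, passed for wild-type p53 targets, JNK and AP-1, the TGF-beta response, epithelial markers, heat shock, and fibroblast and endothelial markers (adjusted p = 0.0406, 0.0261, 0.00663, 0.0406, 0.0103 and 0.00465), and not for interferon-stimulated genes (0.128). Over all kept probes camera also called JNK and AP-1, the TGF-beta response and heat shock (0.0172, 0.0143 and 0.0422). Up and down calls numbered 3 and 0 of 23 for wild-type p53 targets (median 0.09, adjusted p = 0.436), although CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.99 ± 0.16, and 3 and 1 of 22 for JNK and AP-1, where JUNB rose by 1.25 ± 0.12. They numbered 7 and 2 of 22 for the TGF-beta response, with the receptor TGFBR2 at 0.99 ± 0.10 and the matrix protein TGFBI at -0.89 ± 0.14. They numbered 3 and 2 of 13 for epithelial markers, 2 and 1 of 17 for mesenchymal markers, 3 and 0 of 24 for hypoxia, 1 and 4 of 21 for heat shock and oxidative stress, 0 and 1 of 10 for leukocyte markers, and 3 and 0 of 9 for fibroblast and endothelial markers. Adjusted over the list alone, these counts became 3 and 1 for p53 targets, 4 and 1 for JNK and AP-1, 8 and 4 for the TGF-beta response, 3 and 2 for mesenchymal markers, 3 and 4 for heat shock and 3 and 1 for fibroblast and endothelial markers, and did not move for the others. The chemokine CCL5 was at 0.45 ± 0.19 (adjusted p = 0.195) and passed only in a fit of the compared groups alone (adjusted p = 0.0185).

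In all, limma called 1199 of 12507 genes for TNF in control siRNA cells, 612 higher and 587 lower, of which 187 were at least 2-fold higher and 88 at least 2-fold lower. The count was 793 with median scaling and 2215 with array weights, and it was 771, 798 and 736 without control untreated replicate 1, 2 or 3, 764 and 733 without control TNF replicate 1 or 3, and 1906 without p53 siRNA untreated replicate 3. The interferon list lost its call without control untreated replicate 3 (adjusted p = 0.0641) or control TNF replicate 1 (0.0525), with the filter on all 12 arrays (0.0670) and over all kept probes (0.0787). The cholesterol list lost its call without control untreated replicate 1 (0.0558), control untreated replicate 3 (0.0641) or control TNF replicate 1 (0.0629), and with median scaling (0.0651). The proteasome list lost its call without control untreated replicate 1 (0.0635) and with median scaling (0.0565), and fibroblast and endothelial markers gained one without control untreated replicate 2 (0.0466) or control TNF replicate 1 (0.0302).

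In p53 siRNA cells TNF raised many of the same cytokine genes. IL32 rose by 4.32 ± 0.20, IL6 by 3.76 ± 0.17, the chemokine CCL20 by 3.41 ± 0.15, PTGS2 by 3.30 ± 0.16, IL1A by 3.12 ± 0.26, IL1B by 2.88 ± 0.11, CXCL8 by 2.86 ± 0.14 and CXCL10 by 2.59 ± 0.15. PI3, the elastase inhibitor elafin, rose by 3.27 ± 0.17 and was undetected in untreated control siRNA cells. LTB was at least 7.76-fold higher and EBI3 at least 2.23-fold higher (adjusted p = 4.09e-07 and 7.78e-05), both undetected on all untreated p53 siRNA arrays, although another LTB probe gave a log2 change of 1.52, while MMP9 stayed undetected on all 6 p53 siRNA arrays. The largest falls named for control siRNA cells recurred, with CGNL1 at -2.49 ± 0.14, ALDH3A1, detected on 2 of 3 TNF arrays, at -2.17 ± 0.22, TFF3 at -1.48 ± 0.14 and TFF2 at -1.10 ± 0.14. PI3, CXCL10, TNFAIP3 and MMP1 were each detected on 2 of the 3 untreated p53 siRNA arrays.

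Among cytokines and chemokines 17 of 27 rose and 1 fell (22 and 1 adjusted over the list alone; median 1.59, adjusted p = 4.28e-26), and the median was 1.16 with undetected members at their bound. NF-kB regulators rose in 14 of 20 (17 adjusted over the list alone; median 0.85, adjusted p = 4.6e-20). TNFAIP3 was at 2.10 ± 0.15, RELB at 1.58 ± 0.12, NFKB2, a further NF-kB subunit, at 1.42 ± 0.15, NFKBIA at 1.07 ± 0.12 and TNIP1 at 1.06 ± 0.10. The acute phase list had 10 of 19 up (12 up and 1 down adjusted over the list alone; median 0.66, adjusted p = 7.72e-12). SOD2 was at 2.82 ± 0.11 and SAA1 at 1.99 ± 0.18. The adhesion list had 10 of 19 up (13 up and 1 down adjusted over the list alone; median 0.47, adjusted p = 1.1e-09). MMP1 was at 2.72 ± 0.21, ICAM1 at 2.07 ± 0.20 and the matrix protein TNC at 1.15 ± 0.12. The unfolded protein list had 6 of 22 up and 1 down (10 and 2 adjusted over the list alone; median 0.31, adjusted p = 0.000125). CEBPB was at 1.18 ± 0.14 and DNAJB9 at 0.89 ± 0.14. The proteasome list had 1 of 28 up (0 adjusted over the list alone; median 0.21, adjusted p = 0.000194). In the mitosis list 13 of 35 fell (21 adjusted over the list alone; median -0.52, adjusted p = 4.43e-10, but adjusted p = 0.0645 with an estimated correlation). The kinesin KIF20A was at -0.90 ± 0.14 and the kinase PLK1 at -0.84 ± 0.14. In the replication list 6 of 33 fell (18 adjusted over the list alone; median -0.36, adjusted p = 1.51e-07, but adjusted p = 0.181 with an estimated correlation). Antigen presentation had 3 of 19 up (4 adjusted over the list alone; median 0.16, adjusted p = 0.0136, but adjusted p = 0.333 with an estimated correlation). Hypoxia had 4 of 24 up (4 adjusted over the list alone; median 0.09, adjusted p = 0.0294, but adjusted p = 0.260 with an estimated correlation).

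The remaining 11 lists were not called by camera for TNF in p53 siRNA cells. Fry passed for death receptor genes, JNK and AP-1, leukocyte markers, and fibroblast and endothelial markers (adjusted p = 4.21e-07, 0.0189, 0.0343 and 0.0164), and not for antigen presentation (0.0713). Interferon-stimulated genes had 1 up and 3 down of 37, with ISG20 at 1.21 ± 0.18 and IFIT1, an interferon-induced RNA-binding protein, at -1.56 ± 0.11, although another IFIT1 probe gave -0.02. Up and down calls numbered 6 and 3 of 23 for death receptor genes, where TNFRSF9 rose by 1.99 ± 0.13 and BID by 1.14 ± 0.12 (other BID probes from -0.19 to 1.25), 1 and 3 of 22 for the TGF-beta response, where TGFBI fell by 1.01 ± 0.14, and 3 and 0 of 22 for JNK and AP-1. They numbered 3 and 1 of 23 for wild-type p53 targets, where the median was -0.05, or 0 with undetected members at their bound, and the camera test pointed up. Cholesterol synthesis had 0 and 1 of 20, epithelial markers 1 and 4 of 13, mesenchymal markers 2 and 2 of 17, heat shock 0 and 0 of 21, leukocyte markers 0 and 1 of 10, and fibroblast and endothelial markers 2 and 0 of 9. For the epithelial and mesenchymal lists median and mean differed in sign. Adjusted over the list alone, the counts became 8 and 4 for death receptor genes, 4 and 2 for p53 targets and 2 and 3 for mesenchymal markers, and did not move for the others. TRAF1 rose by 1.96 ± 0.23, where another probe gave 0.38, and CCL5 was at 0.50 ± 0.19 (adjusted p = 0.150). CDKN1A was at 0.71 ± 0.16 (adjusted p = 0.0166), a call that was lost in a fit of the compared groups alone (adjusted p = 0.131) and without p53 siRNA TNF replicate 1, 2 or 3 (0.0568, 0.0623 and 0.0564).

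The calls for TNF in p53 siRNA cells numbered 976, 494 higher and 482 lower. Of these, 309 of the higher genes were also higher in control siRNA cells, where independent calls would share 24.2, and 215 of the lower genes were also lower, where they would share 22.6, and 1 gene was called in opposite directions. The count was 542 with median scaling, 310 in a fit of the compared groups alone, 1730 without p53 siRNA untreated replicate 3, and 579, 553 and 582 without p53 siRNA TNF replicate 1, 2 or 3. The antigen presentation list lost its call without p53 siRNA untreated replicate 2 or 3 (adjusted p = 0.177 and 0.117), as did the hypoxia list (0.0840 and 0.265, and 0.0769 with array weights), and the JNK and AP-1 list gained one without control untreated replicate 1 (0.0475) or p53 siRNA untreated replicate 3 (0.0121). That list was also called without a detection filter (0.0305), over all kept probes (0.0330), with the mean of a gene's probes (0.0156) and with array weights (0.0182), and the epithelial list with only probes detected on all 12 arrays (-0.38, 0.00541).

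The third comparison set the siRNAs side by side in untreated cells. Cell division and interferon-stimulated genes were lower in p53 siRNA cells, list calls that were lost with an estimated correlation. CCNA1, a cyclin detected on 1 of the 3 p53 siRNA arrays, was at -3.60 ± 0.19 on the log2 scale. CHAF1B, a subunit of a chromatin assembly factor, was at -3.36 ± 0.19 and OASL, an interferon-induced gene, at -2.96 ± 0.17. HPRT1, an enzyme of purine salvage, was at -2.85 ± 0.12 and MAOA, a monoamine oxidase, at -2.66 ± 0.24, each with an adjusted p of 1.18e-05 or less. Among the largest rises were PTGS2 at 2.72 ± 0.16, HPGD, which breaks down prostaglandins, at 2.51 ± 0.23, the transcriptional regulator CITED1 at 2.50 ± 0.15, the stress cytokine GDF15 at 2.49 ± 0.16, TCN1, a vitamin B12 binding protein, at 2.46 ± 0.20, and BMF, a pro-apoptotic BCL2 family member, at 2.36 ± 0.12.

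Of 33 replication genes 30 fell and 0 rose (30 and 0 adjusted over the list alone; median -1.48, adjusted p = 4.44e-21, but adjusted p = 0.0686 with an estimated correlation). TYMS was at -2.20 ± 0.13, POLE2 at -2.02 ± 0.11 and MCM2 at -1.78 ± 0.12. Of 35 mitosis genes 30 fell (32 adjusted over the list alone; median -1.07, adjusted p = 6.78e-17, but adjusted p = 0.0560 with an estimated correlation). The checkpoint protein MAD2L1 was at -2.55 ± 0.15 (another probe -1.02), the kinase CDK1 at -1.86 ± 0.17 and AURKB at -1.82 ± 0.12. Of 37 interferon-stimulated genes 24 fell and 1 rose (29 and 1 adjusted over the list alone; median -0.90, adjusted p = 3.67e-11, but adjusted p = 0.0800 with an estimated correlation). IFIT1 was at -2.36 ± 0.11 (another probe -0.34), the ubiquitin-like ligase HERC5 at -1.86 ± 0.15 and IFIT2 at -1.66 ± 0.11. Proteasome subunits fell in 12 of 28 (14 adjusted over the list alone; median -0.31, adjusted p = 2.14e-05, and adjusted p = 0.0277 with an estimated correlation), led by PSMC1 at -1.05 ± 0.11 and PSMA2 at -1.29 ± 0.19. In the cholesterol synthesis list 7 of 20 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.0421, but adjusted p = 0.0960 with an estimated correlation). INSIG1, a regulator of sterol sensing, was at -1.54 ± 0.10 and the thiolase ACAT2 at -1.10 ± 0.10.

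The other 16 lists were not called by camera between the siRNAs in untreated cells, many with members in both directions. Fry passed for 10 of them, with an adjusted p of 4.33e-05 for cytokines and chemokines, 0.000875 for adhesion genes, 0.00314 for NF-kB regulators, 0.00446 for wild-type p53 targets and 0.00675 for heat shock. It was 0.0115 for epithelial markers, 0.0119 for hypoxia, 0.0140 for antigen presentation, 0.0282 for JNK and AP-1 and 0.0367 for the acute phase list. Up and down calls numbered 9 and 1 of 27 for cytokines and chemokines, where the macrophage growth factor CSF1 rose by 1.80 ± 0.18, IL1B by 2.09 ± 0.11 and CXCL8 by 1.45 ± 0.14 and IL1A was at least 4.84-fold higher (adjusted p = 1.68e-05). They numbered 7 and 2 of 20 for NF-kB regulators, 5 and 2 of 19 for adhesion genes with SERPINE2 at 1.40 ± 0.15, 3 and 7 of 19 for antigen presentation with the peptide transporters TAP1 at -1.71 ± 0.18 and TAP2 at -1.85 ± 0.19, and 1 and 3 of 19 for the acute phase list with the methyltransferase NNMT at -2.79 ± 0.24. They numbered 6 and 4 of 23 for wild-type p53 targets, where the stress protein SESN1 rose by 0.89 ± 0.11 and DDB2, a DNA repair factor, fell by 1.35 ± 0.23, and 4 and 6 of 23 for death receptor genes, where CFLAR rose by 1.0 ± 0.12. Heat shock and oxidative stress had 11 and 4 of 21, with the haem oxygenase HMOX1 at 1.30 ± 0.20, hypoxia 3 and 10 of 24, with the peptide hormone ADM at 1.15 ± 0.15, and unfolded protein stress 5 and 3 of 22, with the serine synthesis enzyme PSAT1 at -1.52 ± 0.14. JNK and AP-1 had 4 and 2 of 22, the TGF-beta response 10 and 7 of 22 with ID1 at -1.35 ± 0.23, epithelial markers 1 and 3 of 13 with the keratin KRT7 at -1.07 ± 0.16, and mesenchymal markers 2 and 5 of 17 with PRRX1 at 1.84 ± 0.18 and the collagen cross-linking enzyme LOX at 1.72 ± 0.19. Leukocyte markers had 3 and 2 of 10 and fibroblast and endothelial markers 4 and 3 of 9, and for both lists median and mean differed in sign. Adjusted over the list alone, the counts became 0 and 3 for the acute phase list, 5 and 6 for death receptor genes, 11 and 7 for the TGF-beta response, 2 and 6 for mesenchymal markers, 3 and 12 for hypoxia, 11 and 6 for heat shock and 4 and 4 for fibroblast and endothelial markers, and did not move for the others.

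Several TNF target genes did not differ between the siRNAs in untreated cells by the test. IL6 was at -0.02 ± 0.17, TNFAIP3 at 0.00 ± 0.15, MMP1 at 0.04 ± 0.21, CXCL10 at -0.28 ± 0.15 and CCL5 at -0.12 ± 0.19, each with an adjusted p of 0.160 or more, and MMP9 was undetected in both groups. ICAM1 was at 0.32 ± 0.20 and passed without control untreated replicate 1 (0.58, adjusted p = 0.0216), and TRAF1 was at 0.27 ± 0.23 and passed without p53 siRNA untreated replicate 3 (0.54, adjusted p = 0.0360). NFKBIA was at 0.46 ± 0.12 (adjusted p = 0.00992), a call lost with median scaling (adjusted p = 0.241) and in a fit of the compared groups alone (0.0653). CDKN1A was at 0.49 ± 0.16 (adjusted p = 0.0310), a call lost with median scaling (0.165), in a fit of the compared groups alone (0.118), without control untreated replicate 1, 2 or 3 (0.0699, 0.0803 and 0.0668) and without p53 siRNA untreated replicate 1 or 2 (0.104 and 0.0984).

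For p53 siRNA in untreated cells 4458 genes were called, 2215 higher and 2243 lower, with 344 at least 2-fold higher and 625 at least 2-fold lower. With each array scaled to a common median the median of all genes was -0.14, against 0.01 before, with 909 higher and 2773 lower calls, and a fit of the compared groups alone gave 2954. Relative to that median the list medians were -1.49 for replication, -1.16 for mitosis, -0.86 for interferon-stimulated genes, -0.39 for the proteasome and -0.22 for cholesterol synthesis. The cholesterol list lost its call without control TNF replicate 1 (adjusted p = 0.0511) or p53 siRNA untreated replicate 1 (0.0823), with the mean of a gene's probes (0.0869) and in a fit of the compared groups alone (0.0660). Without control untreated replicate 1 the cytokine and adhesion lists gained a call (adjusted p = 0.0414 and 0.0444). The cytokine list was also called with median scaling (0.00416) and over all kept probes (0.29, 0.00176), and the hypoxia list with median scaling (0.0372), without a detection filter (0.0459) and over all kept probes (0.0280).

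In TNF-treated cells the p53 siRNA was likewise accompanied by lower interferon-stimulated and cell division genes. The replication list lost its call with an estimated correlation. IFIT1 was at -3.60 ± 0.11 on the log2 scale (another probe -0.43), and NLRP3, an inflammasome sensor, at -3.07 ± 0.10. NNMT was at -3.09 ± 0.24 and CCNA1 at -2.65 ± 0.19, both detected on 2 of 3 p53 siRNA arrays. MAOA was at -3.05 ± 0.24, OASL at -2.75 ± 0.17 and HPRT1 at -2.68 ± 0.12, and each of these genes had an adjusted p of 6.56e-06 or less. MMP9, detected on the 3 control arrays and on 0 of the 3 p53 siRNA arrays, was at least 5.83-fold lower (adjusted p = 1.81e-09), and CASP1, the caspase that matures interleukin 1 beta, at least 3.88-fold lower (adjusted p = 2.81e-06). TCN1 rose by 3.40 ± 0.20, GDF15 by 3.25 ± 0.16, HPGD by 2.95 ± 0.23, CITED1 by 2.74 ± 0.15, PI3 by 2.68 ± 0.17 and AKR1C2, an aldo-keto reductase, by 2.65 ± 0.16.

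Interferon-stimulated genes fell in 29 of 37 with 0 rising (30 and 0 adjusted over the list alone; median -1.09, adjusted p = 8.97e-16, and adjusted p = 0.0313 with an estimated correlation). IFIT2 was at -2.29 ± 0.11 and HERC6 at -2.01 ± 0.16. Mitosis genes fell in 29 of 35 (32 adjusted over the list alone; median -1.14, adjusted p = 1.02e-16, and adjusted p = 0.0313 with an estimated correlation). MAD2L1 was at -2.15 ± 0.15 (another probe -1.20) and the kinase AURKA at -1.71 ± 0.16. Replication genes fell in 28 of 33 (28 adjusted over the list alone; median -1.02, adjusted p = 8.97e-16, but adjusted p = 0.0766 with an estimated correlation). MCM6 was at -1.84 ± 0.17 and TYMS at -1.79 ± 0.13. Cholesterol synthesis fell in 9 of 20 (10 adjusted over the list alone; median -0.38, adjusted p = 0.00111, and adjusted p = 0.0313 with an estimated correlation). INSIG1 was at -1.58 ± 0.10 and the kinase MVK at -0.97 ± 0.11. The proteasome list had 9 of 28 down (9 adjusted over the list alone; median -0.24, adjusted p = 0.000173, and adjusted p = 0.0313 with an estimated correlation). PSMC1 was at -1.08 ± 0.11 and PSMA1 at -0.74 ± 0.10. Antigen presentation had 8 of 19 down (8 adjusted over the list alone; median -0.16, adjusted p = 0.00499, but adjusted p = 0.298 with an estimated correlation). TAP2 was at -2.12 ± 0.19 and TAP1 at -1.93 ± 0.18. The acute phase list had 11 of 19 down and 4 up (12 and 4 adjusted over the list alone; median -0.43, adjusted p = 0.00896, but adjusted p = 0.120 with an estimated correlation). The protease inhibitor SERPINA3 was at -1.61 ± 0.14, detected on 2 of 3 p53 siRNA arrays. Epithelial markers had 5 of 13 down (6 adjusted over the list alone; median -0.35, adjusted p = 0.0192, but adjusted p = 0.0766 with an estimated correlation). Of the keratins, KRT7 was at -1.13 ± 0.16 and KRT19 at -0.51 ± 0.10.

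The cytokines split under TNF, with 8 of 27 higher and 9 lower in p53 siRNA cells and no camera call of the list (median 0.11, mean -0.09, adjusted p = 0.834). LTB was at -2.18 ± 0.20, EBI3 at -2.15 ± 0.17 and CXCL10 at -2.05 ± 0.15, whereas IL1A rose by 1.99 ± 0.26 and IL1B by 1.22 ± 0.11. TNFAIP3 was at -0.78 ± 0.15, TNIP1 at -0.65 ± 0.10, ICAM1 at -0.79 ± 0.20 and the urokinase PLAU at -1.55 ± 0.18, and MMP1 rose by 1.06 ± 0.21. IL6 was at 0.11 ± 0.17, NFKBIA at -0.16 ± 0.12, CCL5 at -0.07 ± 0.19 and TRAF1 at -0.02 ± 0.23 (another probe -0.52), each with an adjusted p of 0.349 or more, and CDKN1A was at 0.21 ± 0.16 (adjusted p = 0.343, and 0.0404 without p53 siRNA untreated replicate 3). CXCL8 was at 0.46 ± 0.14 (adjusted p = 0.0281), a call lost with median scaling (0.224), without control TNF replicate 1, 2 or 3 (0.0840, 0.0525 and 0.0689) and without p53 siRNA TNF replicate 1 or 2 (0.0958 and 0.0990). Up and down calls numbered 2 and 6 of 20 for NF-kB regulators and 7 and 5 of 19 for adhesion genes, where the median was 0.17 and the mean -0.08. They numbered 4 and 3 of 23 for wild-type p53 targets with DDB2 at -1.61 ± 0.23, 3 and 9 of 23 for death receptor genes with BMF at 1.99 ± 0.12, and 4 and 2 of 22 for JNK and AP-1. For the TGF-beta response they numbered 6 and 7 of 22, for mesenchymal markers 2 and 6 of 17 with PRRX1 at 1.78 ± 0.18 and LOX at 1.43 ± 0.19, and for hypoxia 2 and 8 of 24. Unfolded protein stress had 5 and 3 of 22, with the transcription factor DDIT3 at 1.29 ± 0.17 and PSAT1 at -1.64 ± 0.14, and heat shock 9 and 2 of 21, with the metallothioneins MT1E at 2.45 ± 0.19 (another probe 1.15) and MT1X at 1.64 ± 0.14. Leukocyte markers had 2 and 1 of 10, and fibroblast and endothelial markers 3 and 2 of 9. Fry passed for 10 of these 13 lists and not for unfolded protein stress, leukocyte markers, or fibroblast and endothelial markers, with an adjusted p from 5.91e-07 for death receptor genes to 0.0453 for the TGF-beta response, and 0.0406 for cytokines and chemokines. For the cytokine and adhesion lists fry pointed down, as their means did, although their medians were above 0. Adjusted over the list alone, the counts became 3 and 8 for NF-kB regulators, 3 and 10 for death receptor genes, 6 and 8 for the TGF-beta response and 5 and 4 for unfolded protein stress, and did not move for the others.

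For p53 siRNA in TNF-treated cells 3863 genes were called, 1799 higher and 2064 lower. Of those higher, 1315 were also higher in untreated cells, where independent calls would share 318.6, and of those lower 1533, where they would share 370.2, and 8 were called in opposite directions. With median scaling the median of all genes was -0.15, against 0.01 before, with 623 higher and 2686 lower calls, and relative to that median the list medians were -1.23 for mitosis, -1.16 for interferon-stimulated genes and -1.09 for replication. No called list in any comparison turned direction under the 3 other scalings, while 11 of the 105 list medians, all of uncalled lists, changed sign with median scaling. The heat shock list passed without control TNF replicate 3 (adjusted p = 0.0432) or p53 siRNA TNF replicate 1 (0.0481), without a detection filter (0.0245) and with the mean of a gene's probes (0.0223). Death receptor genes passed without a detection filter (0.0352), over all kept probes (0.0129) and with the mean of a gene's probes (0.0380), and mesenchymal markers over all kept probes (-0.38, 0.00998). The acute phase and epithelial lists lost their calls when only probes detected on all 12 arrays at 0.01 were used (0.618 and 0.0514).

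**Figure D2:**
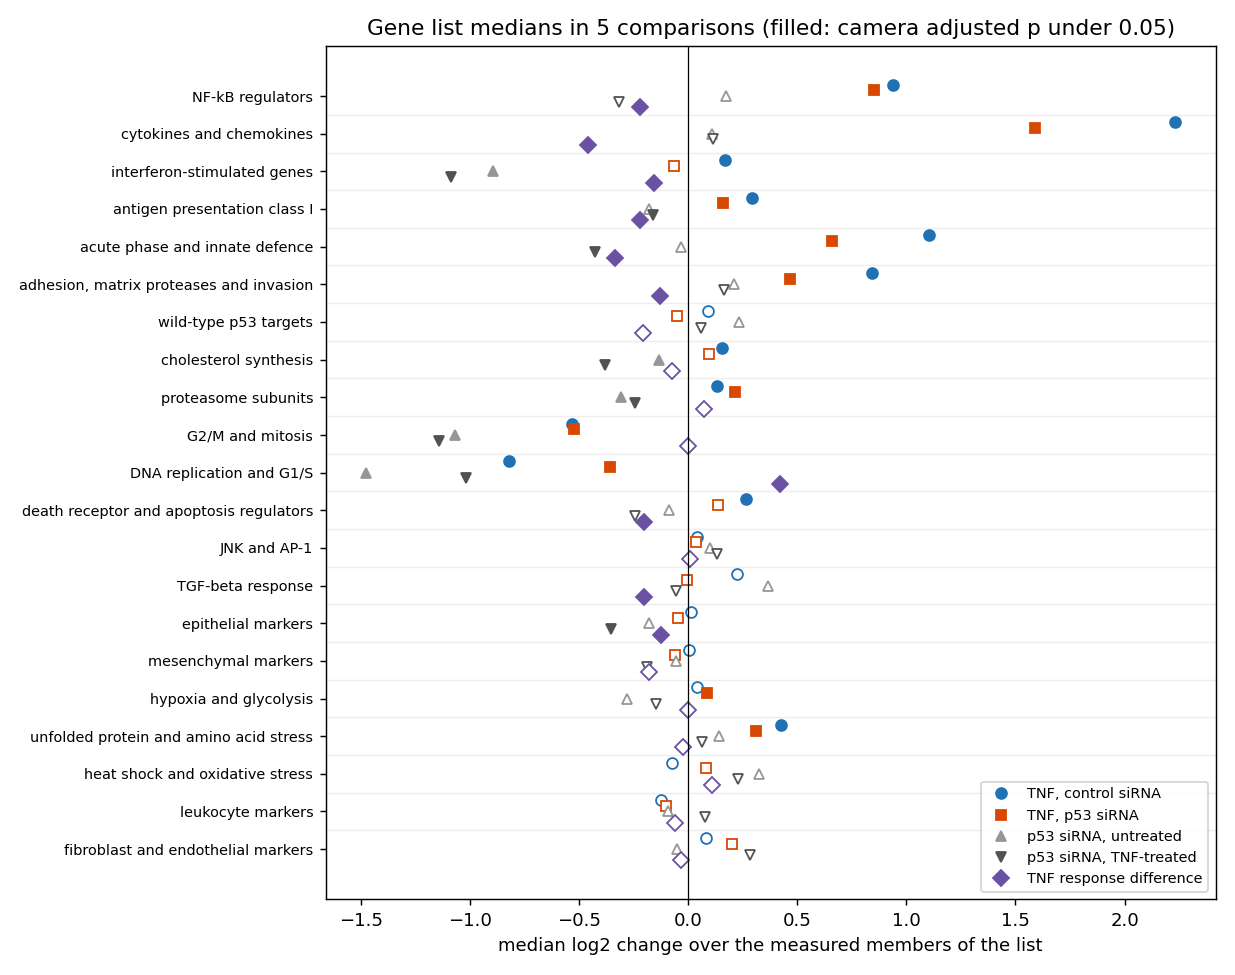
Median log2 change of each of the 21 gene lists in the 5 comparisons, with filled symbols where the camera adjusted p was under 0.05. With TNF in control siRNA cells the cytokine list lay at 2.23 and the replication list at -0.82, and between the siRNAs in untreated cells the replication list lay at -1.48.

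The study's central question, whether the TNF response differed between the siRNAs, was tested as the difference between the 2 TNF effects. The clearest differences were smaller responses in p53 siRNA cells. MMP9 and the cathepsins CTSS and CTSW were detected on all 3 TNF-treated control arrays and on none of the other 9, with adjusted p of 1.43e-07, 0.00558 and 0.00493 for the difference. CXCL10 rose by 4.36 with control siRNA and by 2.59 with p53 siRNA, a difference of -1.77 ± 0.21 (adjusted p = 0.00505). SERPINA3, an acute phase protease inhibitor, differed by -1.54 ± 0.19 (adjusted p = 0.00572), with detection on 1 of 3 arrays in both untreated groups. EBI3, undetected in both untreated groups, was at least 9.98-fold higher with TNF in control siRNA cells and at least 2.23-fold higher in p53 siRNA cells (adjusted p of the difference 0.00505). PI3 went the other way with a larger response in p53 siRNA cells, with a fitted difference of 2.17 ± 0.25 (adjusted p = 0.00505), and was undetected in untreated control siRNA cells. These 7 genes were called in every fit that left out 1 array and kept the gene, and under each of the 9 other ways of processing or fitting that tested it.

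**Figure D3:**
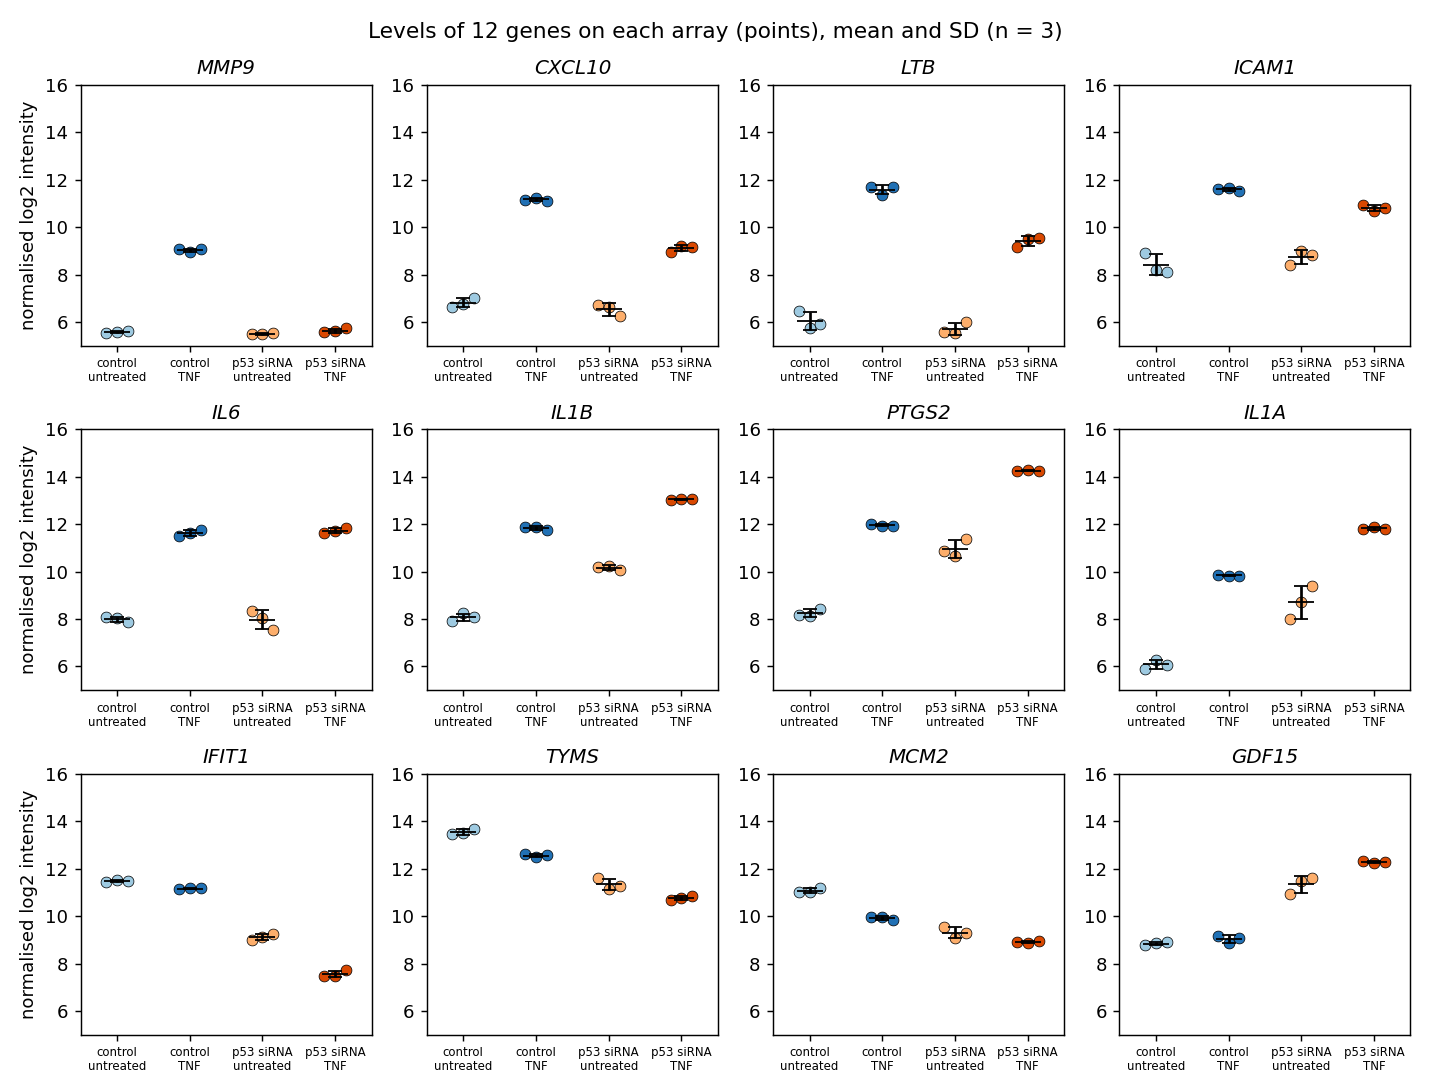
Normalised log2 intensity of 12 genes on each array, with points for arrays and a bar for the mean and SD of 3 arrays, in the 4 groups. MMP9 lay above its level in the other groups on the 3 TNF-treated control arrays alone, and IFIT1 was lowest on the TNF-treated p53 siRNA arrays.

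Limma called 27 genes for the TNF response difference, 17 with a more negative and 10 with a more positive TNF effect in p53 siRNA cells, and 1282 genes had an unadjusted p under 0.05. Further genes that TNF raised in control siRNA cells and less so in p53 siRNA cells were the tryptophan-degrading enzyme IDO1 (detected on 0 of 3 and 3 of 3 control arrays and on 1 of 3 and 2 of 3 p53 siRNA arrays without and with TNF) and LTB at a fitted -1.85 ± 0.28 (adjusted p = 0.0254). The same was seen for TNIP1 at -1.09 ± 0.14, NLRP3 at a fitted -1.08 ± 0.14 (other probes -0.97 and -0.61), undetected on the 3 untreated p53 siRNA arrays, CD82 at -0.76 ± 0.13 (another probe -0.17) and IL1B at -0.87 ± 0.15. IFIT1 instead fell by 1.56 ± 0.11 in p53 siRNA cells and was at -0.32 ± 0.11 (adjusted p = 0.0919) in control siRNA cells, a difference of -1.24 ± 0.15 (another probe -0.09). The remaining genes with a more negative effect were ISM1, SOST, the kinase NUAK2 and STX11. Among the genes with a more positive effect, MT1E fell by 1.52 ± 0.19 in control siRNA cells and was at 0.10 ± 0.19 (adjusted p = 0.810) in p53 siRNA cells, a difference of 1.63 ± 0.27 (another probe 0.12). RGCC likewise fell by 1.65 ± 0.15 and was at -0.46 ± 0.15 (adjusted p = 0.0855), and ZNF300P1 fell by 0.57 ± 0.13 in control and rose by 0.60 ± 0.13 in p53 siRNA cells. The gap junction protein GJA1 and the aldo-keto reductases AKR1C2 and AKR1C4 rose in p53 siRNA cells and were not called in control siRNA cells, with differences of 1.49 ± 0.23, 1.37 ± 0.22 and 1.06 ± 0.17. C11orf96 rose by 1.32 ± 0.13 in control and by 2.35 ± 0.13 in p53 siRNA cells. EOMES and ABCA13 were undetected on all 6 control siRNA arrays and detected on all 3 TNF-treated p53 siRNA arrays. IL6 differed by 0.14 ± 0.24, CCL5 by 0.05 ± 0.27, TRAF1 by -0.29 ± 0.32 and CDKN1A by -0.27 ± 0.22. IL1A, undetected in untreated control siRNA cells, differed by a fitted -0.63 ± 0.36, TNFAIP3 by -0.78 ± 0.21 and MMP1 by 1.02 ± 0.30, and each of these genes had an adjusted p of 0.195 or more. NFKBIA differed by -0.62 ± 0.17 (adjusted p = 0.199, and 0.0321 without p53 siRNA untreated replicate 3), and ICAM1 by -1.11 ± 0.29 (0.183, and 0.0461 with quantile normalisation alone). CXCL8 differed by -0.99 ± 0.20 (0.0840, and 0.0415 without p53 siRNA untreated replicate 3), and it passed with quantile normalisation alone (0.0339), the authors' values (0.0337) and the intensity trend with robust moderation (0.0199). RELB differed by -0.93 ± 0.17 (0.0594, and 0.0199 or 0.0317 without p53 siRNA untreated replicate 1 or 3), and it passed with array weights (0.0292) and the mean of its probes (0.0496).

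The count of 27 depended on single arrays. It was 13, 13 and 15 without control untreated replicate 1, 2 or 3, 8, 12 and 5 without control TNF replicate 1, 2 or 3, 11, 11 and 12 without p53 siRNA TNF replicate 1, 2 or 3, and 133 without p53 siRNA untreated replicate 3, which kept all 27 in the same direction. Median scaling gave 1 higher and 11 lower calls, quantile normalisation alone gave 50, the authors' values gave 52 with 26 in each direction, and a filter on probes detected on all 12 arrays at 0.01 gave 7. IDO1, TNIP1 and NLRP3 were called in 11 of 12 fits that left out 1 array and IFIT1 in all 12, whereas IL1B and SOST were called in 1 of 12, LTB in 5 of 12, and the others, from CD82 and ISM1 to EOMES and GJA1, in 2 to 4. IDO1 and LTB were also called under all 9 other ways of processing or fitting. IFIT1 lost its call with median scaling (adjusted p = 0.0909) and with the mean of its probes (-0.67, 0.127), TNIP1 with median scaling (0.0909), and NLRP3 with the mean of its probes (0.0680) and with the intensity trend and robust moderation (0.0628). The genes called in 1 to 4 of the fits that left out 1 array were called under between 1 of 9 such ways, for SOST, and 8 of 10, for AKR1C2 and AKR1C4. All 27 kept their sign throughout.

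Over the 154 TNF-induced genes the median TNF response difference was -0.15 (camera p = 2.88e-05, and p = 0.0276 with an estimated correlation). Of these genes 91 lay below and 63 above 0, and the median was -0.19 with the 35 genes undetected in a group left out. Their median between the siRNAs was 0.20 without TNF, or 0.13 with undetected genes at their bound, with 55 called higher and 20 lower, and 0.13 with TNF, with 60 higher and 44 lower. Of the 91 genes below 0, with a smaller rise, 31 were called higher untreated in p53 siRNA cells and not called lower under TNF. Of those 31 genes, 21 were also called higher under TNF. Another 36 were called lower under TNF and not called higher untreated, 2 were both higher untreated and lower under TNF, and 22 were neither. Choosing genes below 0 itself favours both classes, so the split does not show how responses shrank. Without p53 siRNA untreated replicate 3 the median over the TNF-induced genes was -0.03 and no longer passed the camera test. It still passed at -0.07 without p53 siRNA untreated replicate 2, -0.07 with quantile normalisation alone, -0.09 with array weights and -0.24 with median scaling. With the genes chosen on control siRNA cells alone it was -0.38, and on p53 siRNA cells alone 0.16. Over 59 TNF-repressed genes the median was -0.10 and did not pass that test, while it passed at -0.24 and -0.16 without p53 siRNA untreated replicate 2 or 3.

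**Figure D4:**
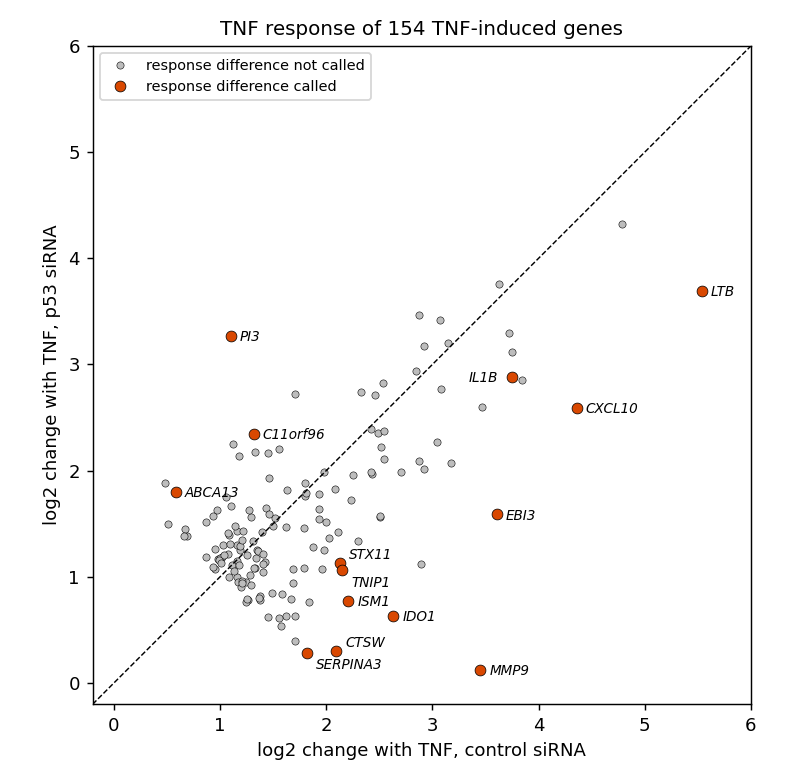
Log2 change with TNF in p53 siRNA cells (vertical) against control siRNA cells (horizontal) for 154 TNF-induced genes, with genes called for the response difference in orange and the dashed line marking equal responses. Fitted values of genes undetected in a group, such as MMP9 at 3.45 and 0.12, are plotted as fitted and are no bounds.

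Of the gene lists, 9 had a more negative and 1 a more positive TNF effect in p53 siRNA cells. Cytokines and chemokines had a median difference of -0.46 with 0 genes called higher and 4 lower of 27 (0 and 10 adjusted over the list alone; adjusted p = 2.81e-07, and adjusted p = 0.0104 with an estimated correlation), and -0.31 over members detected in each group. NF-kB regulators had -0.22 with 0 and 1 of 20 (0 and 6 adjusted over the list alone; adjusted p = 0.000118, and adjusted p = 0.0163 with an estimated correlation). Death receptor genes had -0.20 with 0 and 0 of 23 (0 and 2 adjusted over the list alone; adjusted p = 0.00274, and adjusted p = 0.0417 with an estimated correlation), where TNFRSF9 was at -0.43 ± 0.19. Replication genes, which fell with TNF, had 0.42 with 0 and 0 of 33 (12 and 0 adjusted over the list alone; adjusted p = 1.31e-12, but adjusted p = 0.110 with an estimated correlation). MCM2 was at 0.77 ± 0.18 and the primase PRIM1 at 0.84 ± 0.20, and both passed with quantile normalisation alone (adjusted p = 0.0371 and 0.0402) and with the authors' values (0.0414 and 0.0425). The acute phase list had -0.34 with 1 and 2 of 19 (2 and 9 adjusted over the list alone; adjusted p = 0.00123, but adjusted p = 0.104 with an estimated correlation). Antigen presentation had -0.22 with 0 and 0 of 19 (0 and 0 adjusted over the list alone; adjusted p = 0.0179, but adjusted p = 0.381 with an estimated correlation). Interferon-stimulated genes had -0.16 with 0 and 1 of 37 (0 and 3 adjusted over the list alone; adjusted p = 0.00330, but adjusted p = 0.352 with an estimated correlation). The TGF-beta response had -0.20, adhesion genes -0.13 and epithelial markers -0.13 (adjusted p = 0.00892, 0.00264 and 0.0417, but each with an adjusted p = 0.110 with an estimated correlation). These had 0 and 0 of 22, 0 and 2 of 19 and 0 and 0 of 13 called, and 0 and 0, 1 and 4 and 0 and 1 adjusted over the list alone.

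The other 11 lists were not called by camera for the TNF response difference. Of these, heat shock and oxidative stress passed by fry (adjusted p = 0.0286) and by camera with quantile normalisation alone (0.0467), median scaling (0.0281), all kept probes (0.0444) and the mean of a gene's probes (0.0287). Of the called lists, interferon-stimulated genes and antigen presentation did not pass by fry (0.189 and 0.243). Their median differences lay between -0.21 for wild-type p53 targets (adjusted p = 0.463) and 0.11 for heat shock and oxidative stress (adjusted p = 0.0768), with 1 gene called higher, MT1E, and 0 lower. Adjusted over the list alone, 1 and 0 were called for p53 targets, 1 and 1 for JNK and AP-1, 3 and 1 for heat shock, 0 and 1 for leukocyte markers, and 0 and 0 for the others. For JNK and AP-1 and for hypoxia the median and the mean differed in sign, and the other lists were mesenchymal markers at -0.18, cholesterol synthesis at -0.08, leukocyte markers at -0.06, fibroblast and endothelial markers at -0.03, unfolded protein stress at -0.03, mitosis at 0.00 and the proteasome at 0.07. With genes undetected in a group left out, the medians were -0.15 for death receptor genes, -0.13 for the TGF-beta response, -0.27 for p53 targets, 0.04 for leukocyte markers and -0.16 for fibroblast and endothelial markers. The interferon and antigen presentation lists lost their calls without p53 siRNA untreated replicate 1 (medians -0.01 and 0.01, adjusted p = 0.166 and 0.259), and the adhesion list without control TNF replicate 1, 2 or 3 (0.262, 0.238 and 0.258). The epithelial list lost its call without control untreated replicate 1 (0.0587), control TNF replicate 1 or 3 (0.0603 and 0.0688), p53 siRNA untreated replicate 1 or 2 (0.166 and 0.0672) or p53 siRNA TNF replicate 3 (0.0913), and the mitosis list gained one without p53 siRNA untreated replicate 1 (0.18, adjusted p = 0.0115). Without a detection filter the adhesion and epithelial lists lost their calls (0.0896 and 0.109). With only probes detected on all 12 arrays at 0.01, the cytokine list lost its call (-0.14, adjusted p = 0.0866), as did antigen presentation (0.0506), acute phase (0.386) and adhesion genes (0.0826).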

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

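The tests of the untreated level and of levels near background were chosen only after the results they bear on were seen.

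Values in this part drew attention because the TNF response difference passed its test. It did for 27 genes and 10 gene lists, of which 3 lists held with an estimated correlation. Other splits by siRNA label within each treatment were drawn, 100 of 200 possible ones, and 4 of them, the real one included, gave as many genes as the real 27. The highest of the others was 974, and 3 splits, with 813, 346 and 974 genes, kept all 6 labels of 1 treatment and 2 of the 6 labels of the other. They turn the siRNA effect around in 1 treatment, which points to a structure of the samples, and the median over the other drawn splits was 0. For the lists 4 of 100 splits gave as many as the real 10, with 12 as the highest of the others. The p53 siRNA changed 4458 genes in untreated and 3863 in TNF-treated cells, and mixed labels put that effect into the spread between arrays. These splits therefore do not stand for an unchanged TNF response, and they decide nothing about chance.

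The fitted log2 differences of the genes with a more negative TNF effect in p53 siRNA cells were -3.33 for MMP9, -2.02 for EBI3, -2.0 for IDO1, -1.85 for LTB, -1.79 for CTSW, -1.77 for CXCL10, -1.54 for SERPINA3 and -1.52 for CTSS. They were -1.43 for ISM1, -1.42 for SOST, -1.40 for NUAK2, -1.24 for IFIT1, -1.09 for TNIP1, -1.08 for NLRP3, -1.0 for STX11, -0.87 for IL1B and -0.76 for CD82. MMP9, CTSS, CTSW and NUAK2 were detected on the 3 TNF-treated control arrays and on 0 of the other 9, and EBI3 and STX11 on all 6 TNF-treated arrays and 0 of the untreated ones. SOST was detected on the 3 TNF-treated control arrays and on 2 of 3 untreated p53 siRNA arrays, and LTB and NLRP3 were undetected on the untreated p53 siRNA arrays, so for these genes the fitted value is no bound. Genes with a more positive effect had differences of 2.17 for PI3, 1.63 for MT1E, 1.49 for GJA1, 1.37 for AKR1C2, 1.30 for EOMES, 1.21 for ABCA13, 1.19 for RGCC, 1.18 for ZNF300P1, 1.06 for AKR1C4 and 1.03 for C11orf96. ABCA13 was detected on the 3 TNF-treated p53 siRNA arrays and on 0 of the other 9, and EOMES on those 3 and on 1 of 3 untreated p53 siRNA arrays.

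The lists' median differences were -0.46 for cytokines and chemokines, -0.34 for acute phase and innate defence, -0.22 for NF-kB regulators, -0.22 for class I antigen presentation, -0.20 for death receptor genes, -0.20 for the TGF-beta response, -0.16 for interferon-stimulated genes, -0.13 for adhesion genes, -0.13 for epithelial markers and 0.42 for DNA replication. With an estimated correlation the cytokine, NF-kB and death receptor lists held (adjusted p = 0.0104, 0.0163 and 0.0417). The calls of the others were lost (adjusted p of 0.104 or more).

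The TNF-induced genes rose less in p53 siRNA cells, with a median difference of -0.153 over 154 genes. Compression of dim genes by background is argued against by the brighter 77 genes, whose median was -0.219 ± 0.0878 (bootstrap SE). The untreated p53 siRNA array that stands apart may account for the shift, since without it the median was -0.0263 over the 167 genes then selected and no longer passed the camera test. A higher untreated level that leaves less room to rise stays open. The 56 genes whose untreated level was not higher had a median of -0.109 (bootstrap SE 0.109), although their camera test passed. Noise in that level enters the difference with opposite sign, so this choice pushes the median up. Among the 100 drawn splits 10 gave a median as far from 0, the largest of the others being 0.232, which for the reason given above decides nothing, and a biological effect of the p53 siRNA on the induced genes as a set remains untested beyond this.

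DNA replication genes fell less with TNF in p53 siRNA cells, with a median difference of 0.42. Levels near background in p53 siRNA cells are argued against, since the median TNF-treated level there lay 3.31 log2 units above the lowest detected level. The array that stands apart is argued against as the whole source, since without it the median was 0.338 (camera adjusted p = 1.53e-08). Whether the lower untreated level of these genes with p53 siRNA leaves a smaller fall was not tested, and the list's adjusted p was 0.110 with an estimated correlation.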

How the results depend on the processing

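No test in this part was chosen after the results were seen, since all alternatives were fixed before the data were examined. All kept probes, the mean of a gene's probes, no detection filter and the intensity trend with robust moderation moved none of the counts of changed genes, counts of shifted lists or medians of the TNF-induced and TNF-repressed genes past the limits used here, which were 1.5 times for a count and a lost or gained call for a median. The threshold of 0.01 left 588 genes for TNF with control siRNA, 459 for TNF with p53 siRNA, 2790 and 2253 for the p53 siRNA in untreated and TNF-treated cells, and 11 for the TNF response difference. A minimum log2 change of 1 left 275, 242, 969 and 856 genes in the same order of the first 4 comparisons. Both lower the counts by construction. Median scaling gave 793, 542 and 12 genes for TNF with control siRNA, TNF with p53 siRNA and the TNF response difference, array weights gave 2215 for TNF with control siRNA, and for the TNF response difference quantile normalisation without background correction gave 50 and the authors' values 52. The cause was not tested for these. A fit of only the compared groups gave 310 genes for TNF with p53 siRNA and 2954 for the p53 siRNA in untreated cells, while the counts for TNF with control siRNA and for the p53 siRNA in TNF-treated cells went up to 1778 and 5250. The untreated p53 siRNA arrays lay further from their group mean, with root mean square deviations of 0.260, 0.237 and 0.324, than the others at 0.156 to 0.170. The main fit's shared spread therefore lies below that of comparisons with this group, whose counts fell. It lies above that of comparisons without it, whose counts rose. No other cause was tested. That fit gives no value for the TNF response difference, which needs all 4 groups. With only probes detected on all 12 arrays at 0.01, which leaves fewer genes to test, the TNF response difference had 7 genes and 6 shifted lists. With an estimated correlation camera called 6 lists for TNF with p53 siRNA, 1 and 4 for the p53 siRNA in untreated and TNF-treated cells, and 3 for the TNF response difference, and the cause was not tested. Fry, which does not compare a list with other genes, called 15 and 18 lists for the p53 siRNA in untreated and TNF-treated cells. In the latter the adhesion list, with a median of 0.165, pointed down by fry and not by camera, where it was not called. Choosing the TNF-induced genes on the p53 siRNA cells alone turned their median to 0.157, and choosing the TNF-repressed genes on control or p53 siRNA cells alone gave 0.413 or -0.362, shifts that selection on 1 side produces by its own construction.

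Over the 12 fits that each left out 1 array, the counts ran from 733 to 1906 for TNF with control siRNA, from 553 to 1730 for TNF with p53 siRNA, from 3536 to 5077 and from 2844 to 5057 for the p53 siRNA in untreated and TNF-treated cells, and from 5 to 133 for the TNF response difference. The medians ran from -0.230 to -0.0263 for TNF-induced and from -0.243 to 0.133 for TNF-repressed genes. Each highest count of genes was that without untreated p53 siRNA replicate 3, which lay apart from its group, and the cause of the other changes was not tested. Shifted lists ran from 10 to 13, 8 to 11, 4 to 7, 8 to 9 and 8 to 10 in the order of the 5 comparisons. Replicate numbers did not pair the arrays, since of 18 pairs of arrays with the same number 1 had deviations from the group means correlated above 0.1 (from -0.126 to 0.189 across genes, median 0.00329), and 6 of 12 arrays correlated best with an array of their own number. With the replicate block the TNF response difference had 17 genes, the cholesterol list in untreated cells lost its call (adjusted p = 0.0504), 13 named gene calls, all for that difference, were lost, and no other list call changed.

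Of 255 gene values named in the text 196 kept their direction and side of the threshold under every alternative that tested them, and 48 of the 105 list results did. Under the alternatives that kept all arrays 131 gene calls were lost and 11 gained, and for lists 51 were lost and 53 gained, 30 of the gains by fry. Under the fits that left out 1 array 157 gene calls were lost and 7 gained, and 23 list calls were lost and 9 gained. Counts split by direction moved past 1.5 times in 40 of the results with all arrays and in 36 with 1 left out. No list call was lost or gained with the authors' values. Signal over background limits these results in genes undetected in a group, whose fitted changes are no bounds, and the fitted values of such genes change with the background correction. The slide block was not run, since the files give no slide.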

Other observations

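The test of the interferon-stimulated genes in the TNF-treated comparison was chosen only after the result was seen.

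The genes in this paragraph and the next were chosen after their values were seen. With both siRNAs TNF changed genes that the report does not name. KYNU, an enzyme of tryptophan breakdown, rose by 3.47 ± 0.20 on the log2 scale with control siRNA and by 2.60 ± 0.20 with p53 siRNA (3 arrays against 3, adjusted p from limma 5.59e-07 and 7.53e-06). The tight junction protein CLDN1 rose by 2.48 ± 0.22 and 2.36 ± 0.22, and PECAM1, an adhesion molecule of endothelial cells, by 1.37 ± 0.16 and 0.79 ± 0.16, the latter a call that was lost without p53 siRNA TNF replicate 2 (adjusted p = 0.0511). Lower with TNF were BGLAP, which encodes osteocalcin, at -1.97 ± 0.16 and -1.54 ± 0.16, and the lysozyme gene LYZ at -1.71 ± 0.19 and -1.53 ± 0.19, for which another probe gave -0.27 and -0.18.

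Between the siRNAs, several single genes were lower in p53 siRNA cells with and without TNF. MYL9, a myosin light chain, was at -1.15 ± 0.18 in untreated and -1.51 ± 0.18 in TNF-treated cells, and the tropomyosin TPM1 at -1.14 ± 0.12 and -1.18 ± 0.12, although another TPM1 probe gave 0.13 in untreated cells. TLR3, a sensor of double-stranded RNA detected on no p53 siRNA array, was at least 2.03-fold lower in untreated and at least 2.27-fold lower in TNF-treated cells (adjusted p = 0.000167 and 9.49e-06). CASP4, an inflammatory caspase, was at -0.79 ± 0.11 and -0.76 ± 0.11, and the immunoproteasome genes PSMB9 and PSME2 at -1.91 ± 0.27 and -1.08 ± 0.11 in untreated cells and at -2.04 ± 0.27 and -1.02 ± 0.11 in TNF-treated cells. Higher in p53 siRNA cells were the small proteoglycan LUM at 1.74 ± 0.20 and 1.45 ± 0.20, and PPP1R15A, which restores translation after stress, at 0.96 ± 0.15 and 1.05 ± 0.15.

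Interferon-stimulated genes were lower with p53 siRNA, by a list median of -0.90 in untreated cells, where the call was lost with an estimated correlation (adjusted p = 0.0800). The normalisation is argued against, since the median nearest 0 under 3 other normalisations was -0.644. The untreated array that stands apart is argued against, since the TNF-treated comparison, which does not use it, gave -1.09 (camera adjusted p = 8.97e-16, and adjusted p = 0.0313 with an estimated correlation). A control siRNA that itself raised these genes could give the same difference and cannot be told apart from an effect of the p53 siRNA, since 0 arrays of cells without siRNA were analysed here.

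For the comparisons of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. Each other split also mixes the groups compared, so the real changes enter the spread between arrays and gene counts near 0 follow by construction. The splits therefore decide nothing about chance. The real split had the largest count in each gene comparison. The highest other split gave 0 against 1199 for TNF with control siRNA and 1 against 976 with p53 siRNA. It gave 0 against 4458 and 3863 for the p53 siRNA in untreated and TNF-treated cells. The shifted lists numbered 12 against 10 in the highest other split for TNF with control siRNA, 10 against 7 for TNF with p53 siRNA, and 8 against 6 for the p53 siRNA in TNF-treated cells. In untreated cells they numbered 5 against 6, and 4 of the 10 splits gave as many.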
